A study of Rattus norvegicus with 19 samples.

How the data were processed

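The series holds 1 scanner file per rat for 19 rats: renal cortex total RNA, labelled with Cy3 and hybridised in 1 colour to Agilent arrays, per the labels. Vehicle or 65 mg/kg of streptozotocin was injected intravenously 7 days before grouping, 19 rats were injected with streptozotocin and 14 of them used, the diabetic groups were matched on blood glucose and body weight, and kidneys were taken 14 days after grouping, per the labels. Groups were taken from the labels: Sham (n = 5), DKD (n = 7) and DKD+enarodustat (n = 7).

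The deposited scanner files give a Cy3 intensity per spot, quantified with Agilent Feature Extraction 11.5.1.1, per the file headers. The processed intensity was background-subtracted, spatially and multiplicatively detrended and replaced by surrogate values at background, within each array, per the file headers. The authors also deposited a value table of log2 expression for 22739 probes, all of which matched a probe name of the scanner files. Its columns had medians of 8.13 to 8.21 and correlated at 0.9973 to 0.9993 with normexp-corrected, quantile-normalised scanner values; the method and centring behind it are not stated. The submitters' processing notes also name limma, with no version and no step.

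Each array held 62976 spots, of which 58717 were not controls and covered 45598 probe names; 2319 names had several spots. Log2 of the processed intensity was taken, each array's 75th percentile was subtracted, spots marked as outliers were left out, and spots of 1 probe were averaged, which left 65 missing probe values. A probe was kept if it was well above background on at least 5 of the 19 arrays. Probes were named through their accession in a RefSeq gene table of assembly GRCr8, used for names only (21109 probes), or through another probe of the same file name (1977); the other 22512 kept the name in the files. The kept probe with the highest mean stood for each gene, which gave 24217 genes. Probe positions are on rn4, per the file headers.

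The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (statmod 1.5.0, and data.table, version 1.17.8), with lmFit and eBayes, no covariate and 16 residual degrees of freedom. Fold changes are on the log2 scale, errors are the standard errors of that fit, p-values are two-sided and adjusted by Benjamini-Hochberg within a comparison, and the threshold was 0.05. A gene above background on no array of a group is given as a bound: the bright group's mean over the dim group's mean of, per array, the higher of the lowest signal well above background and the gene's own.

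The 28 gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated one, and adjusted over the 28 lists. For 6 of them, on energy metabolism and HIF targets, the test answers the study's question. Counts of members that rose or fell are over all genes tested, and also adjusted over the list alone. With an estimated correlation 0 of 11 list calls held for DKD against Sham, 3 of 9 for DKD+enarodustat against DKD (glycolysis, HIF targets and lipogenesis) and 1 of 20 for DKD+enarodustat against Sham (HIF targets).

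The groups compared, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise. The rule took, for DKD against Sham and DKD+enarodustat against DKD, the 8 largest rises and 8 largest falls past the threshold with non-overlapping groups, leaving out names that are only identifiers. It also took up to 4 members per list with the smallest adjusted p, a fixed set (among them Epo, Vegfa, Egln3, Hif1a, Epas1, Slc2a1, Ldha, Pdk1, Pdk4, Cpt1a, Txnip, Slc5a2, Slc2a2, Pck1, Havcr1 and Lcn2), and the 8 genes with opposite and 8 with equal signs past the threshold in both comparisons with the largest smaller change. For DKD+enarodustat against Sham, genes of the fixed set are given. Some genes that the rule took are not named in the text but stay in the counts of named genes and of tests on them.

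Scripts were tested on simulated data with 200 changed genes among 24217. At log2 sizes of 0.5, 1 and 2 the fit recovered 41.8%, 61.2% and 92.4% of changed genes for DKD against Sham, with 3.7% of calls false. For DKD+enarodustat against DKD it recovered 47.8%, 67.2% and 89.4%, with 3.55% false, and for DKD+enarodustat against Sham 46.3%, 76.1% and 83.3%, with 3.52% false. In a simulation without change camera called 0 of 28 lists, and with 1 list raised by 0.5 it called that list. The simulated genes were drawn independently, so false list calls among correlated members were not tested.

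The number of arrays limits the precision. Arrays of 1 group correlated at 0.9683 to 0.9903. All 19 arrays were scanned on 1 day, so scan date could not act as a batch, while slide held 42.1% of the variance within groups (4.12% in the authors' value table). The first principal component (28.7% of variance) followed the slide (r2 = 0.964) and the second (20.1%) the group (r2 = 0.848) and, less closely, slide row (r2 = 0.529).

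The groups share replicate numbers in the labels. All 17 pairs of arrays with the same number in different groups deviated together from their group means, with correlations of 0.132 to 0.595 (median 0.228), so the numbers were taken as pairs under a threshold of 0.1 fixed in advance. Every such pair also shared a slide, and 22 pairs of different number on 1 slide had a median of 0.253 (0.061 to 0.518), against -0.209 for 80 pairs on different slides; 7 of 19 arrays correlated best with their own number. The pairing therefore follows the slide layout. Blocked values stand beside a result where they change its call or move a count by more than 1.5 times. The replicate block was fitted to the compared groups alone and to the numbers both held. It therefore had fewer arrays and residual degrees of freedom than the main fit.

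Alternatives tried were normexp with quantile normalisation, quantile normalisation or median centring of the processed intensity, the authors' value table, no filter or a filter on all arrays, the mean of a gene's probes or each probe, eBayes with trend and robust, array weights, only the groups compared, other thresholds, slide and replicate number as blocks, and leaving out each array. Added after seeing the data were slide row, slide with slide row, 1 slide row only, single slides, leaving out the DKD arrays of row 2, and slide in the fit for the covariance of fold changes. Only DKD had arrays in both rows. With slide row as a covariate, DKD+enarodustat against DKD therefore set 7 arrays against the 2 DKD arrays of row 2. DKD against Sham set 5 arrays of row 1 against 5. These are the differences of 1 slide row only, with the spread taken from all arrays, so the settings are not independent. Background and mean spot intensities entered only the normexp alternative, and control spots were left out throughout.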

Results

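Gene expression was measured in renal cortex RNA of 19 male Crl:CD (SD) rats, with 1 single-colour Agilent array per animal. The 5 Sham rats received vehicle. The 7 DKD rats received 65 mg/kg of streptozotocin, a toxin of the insulin-producing beta cells. The 7 DKD+enarodustat rats received the same injection and then feed with 0.01% (w/w) of enarodustat, an inhibitor of the prolyl hydroxylases that mark hypoxia-inducible factor (HIF) for degradation. Probes well above background made up 64.3% ± 2.61 (SD, n = 5) of all probes in Sham, 62.8% ± 4.87 (SD, n = 7) in DKD and 58.9% ± 2.87 (SD, n = 7) in DKD+enarodustat. The arrays lay on 3 slides that each held all groups. Row on the slide was tied to group: all 5 Sham arrays lay in row 1 and all 7 DKD+enarodustat arrays in row 2, while DKD had 5 in row 1 and replicates 2 and 4 in row 2. The share of probes above background averaged 64.9% in row 1 and 58.3% in row 2. Of the 24217 genes tested, the median standard error of a log2 difference was 0.15 for DKD against Sham and 0.14 for DKD+enarodustat against DKD.

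The comparison of DKD with Sham asked what streptozotocin diabetes changed in the renal cortex. Havcr1, which encodes the tubular injury marker KIM-1, rose by 4.88 ± 0.65 on the log2 scale (SE, n = 7 and 5, adjusted p = 5.62e-05), and every DKD array lay above every Sham array. That difference was 2.52 with normexp and quantile normalisation and 2.26 in the authors' value table. Cyp24a1, the enzyme that breaks down active vitamin D, rose by 3.85 ± 0.29 (adjusted p = 2.07e-07). Cyp2c11, a male-predominant cytochrome P450, fell by 5.63 ± 0.34 (adjusted p = 1.86e-08), and Slco1a1, an organic anion transporter of the proximal tubule, fell by 4.60 ± 0.56 (adjusted p = 2.39e-05). In the rn4 build of the file headers, the probe of Havcr1 lay on chromosome 10 from 31857202 to 31857261 and that of Cyp2c11 on chromosome 1 from 243320626 to 243320685.

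The other large rises were Car3, a carbonic anhydrase abundant in muscle and fat, by 5.97 ± 1.30 (adjusted p = 0.00391, and a difference of 3.97 in the authors' value table), Abcb1b, a drug efflux pump, by 4.61 ± 0.36 (adjusted p = 2.73e-07), and the cytokine Il24, by 3.92 ± 0.75 (adjusted p = 0.00146, and 1.28 with normexp and quantile normalisation). Creb3l3, a liver-enriched transcription factor, rose by 4.20 ± 0.42 (adjusted p = 3.28e-06), with 1 of 5 Sham arrays above background and 1.08 with normexp and quantile normalisation. The sizes of such differences depend on how signal at background is handled. Cldn14, a tight-junction protein, rose by 3.98 ± 0.44 (adjusted p = 7.44e-06, and 1.83 with normexp and quantile normalisation). Large falls were seen for Anxa13, an epithelial annexin, 54.8-fold (log2 SE 0.83, adjusted p = 0.000112), which stayed above background on 1 of 7 DKD arrays and differed by -1.96 with normexp and quantile normalisation, and for Zfp648, a zinc-finger gene, by 4.46 ± 0.60 (adjusted p = 6.5e-05, and -2.17 with normexp and quantile normalisation). Kap, the androgen-regulated kidney protein, fell by 3.95 ± 0.52 (adjusted p = 5.14e-05), and the trefoil factor Tff3 fell by 3.83 ± 0.56 (adjusted p = 0.000125). Slco1a4, named Slco1a2 in the files, fell by 4.45 ± 0.59 (adjusted p = 5.58e-05, and -2.70 with normexp and quantile normalisation) while its other probe gave -0.54, and Prima1, an anchor of acetylcholinesterase, fell by 4.03 ± 0.32 (adjusted p = 3.6e-07) while its other probe gave -0.92. Car3 was highest in DKD replicates 2 and 4, at 4.13 and 3.97, the DKD arrays that lay in slide row 2 and also had the highest levels of the adipocyte markers Fabp4 and Cfd.

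**Figure D1:**
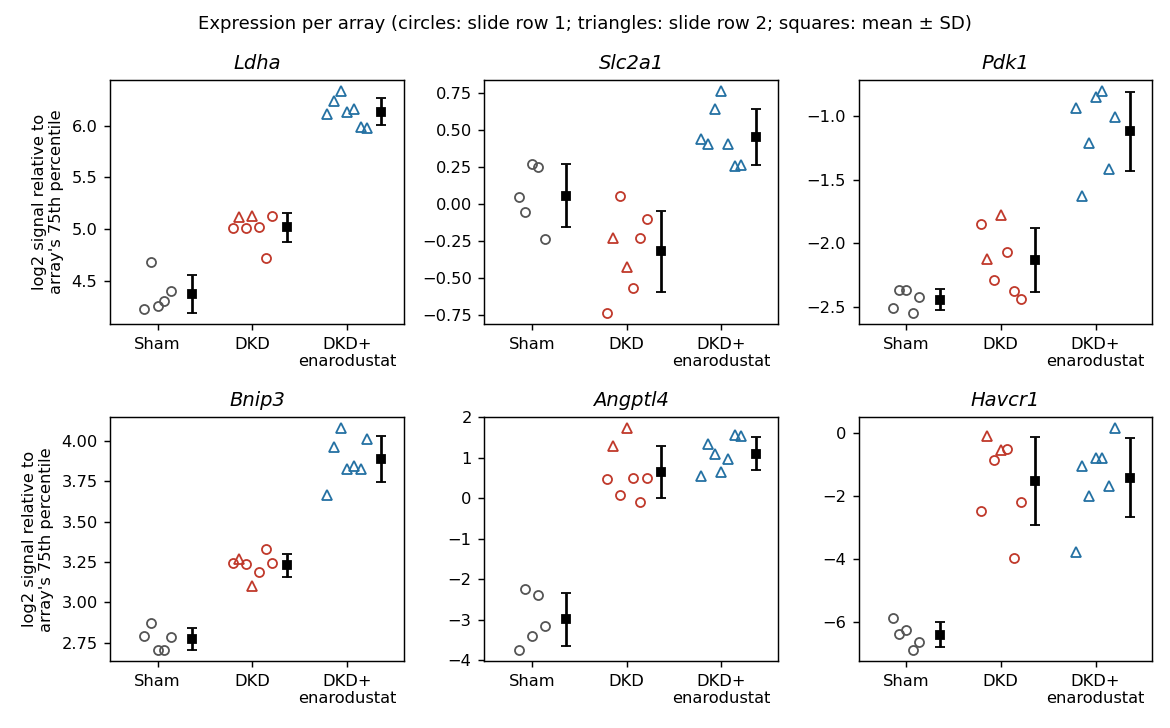
Normalised log2 level of 6 genes on each of the 19 arrays (vertical axis, log2 units above the 75th percentile of the array) by group. Circles are arrays of slide row 1, triangles those of row 2, and squares with bars the group mean ± SD. Ldha rises from 4.37 in Sham to 5.02 in DKD and 6.14 in DKD+enarodustat, while Havcr1 and Angptl4 are higher in both diabetic groups than in Sham.

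Genes of energy metabolism moved unevenly between DKD and Sham. Of 43 measured genes of fatty acid oxidation and PPAR-alpha targets, 26 rose and 1 fell, with a median of 0.40 (28 and 1 when adjusted over the list alone; camera adjusted p = 1.76e-12, and adjusted p = 0.241 with an estimated correlation). Among them Angptl4, an inhibitor of lipoprotein lipase, rose by 3.63 ± 0.32 (adjusted p = 8.24e-07), Pdk4, a kinase that switches off pyruvate dehydrogenase, by 2.78 ± 0.25 (adjusted p = 1.16e-06), and Cyp4a1, a fatty acid hydroxylase, by 1.62 ± 0.20 (adjusted p = 2.26e-05). Pdk4 was above background on 1 of 5 Sham arrays, and its difference was 0.47 with normexp and quantile normalisation. Cpt1a, which carries fatty acids into mitochondria, rose by 0.77 ± 0.21 (adjusted p = 0.016, and 0.0538 without Sham replicate 1). The adipocyte markers moved with this group: 4 of 9 rose and 0 fell, with a median of 1.45 (5 and 0 over the list alone; camera adjusted p = 0.00115, and adjusted p = 0.241 with an estimated correlation), and within slide row 1 their median was 0.63. The fatty acid list itself had a median of 0.42 within row 1 and of 0.37, 0.57 and 0.42 within slides 1, 2 and 3.

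Oxidative phosphorylation genes shifted down by a small amount: 0 of 55 rose and 4 fell, with a median of -0.08 (0 and 0 over the list alone; camera adjusted p = 0.0152). That call ended with an estimated correlation (adjusted p = 0.84), with slide row as a covariate (adjusted p = 0.0715), with each array centred on its median (adjusted p = 0.0786), and without Sham replicate 4 or DKD replicate 2 (adjusted p = 0.0618 and 0.0502). It was stronger with normexp and quantile normalisation, quantile normalisation alone and the authors' value table (camera adjusted p = 5.12e-11, 2.23e-07 and 1.77e-08), so it depends on the normalisation. One member that fell was the complex I subunit Ndufb8, by 0.25 ± 0.07 (adjusted p = 0.0206, and 0.065 with a replicate block). It differed by -0.23 with slide row as a covariate (adjusted p = 0.0641). In glycolysis 3 of 19 genes rose and 1 fell (5 and 4 over the list alone); the median was -0.04, the mean 0.01 and the camera direction up (adjusted p = 0.724). Ldha, lactate dehydrogenase A, rose by 0.65 ± 0.09 (adjusted p = 8.86e-05), and the enolase Eno1 fell by 0.61 ± 0.11 (adjusted p = 0.000698). Among 22 genes of pyruvate dehydrogenase and the TCA cycle 1 rose and 0 fell (1 and 0 over the list alone; median -0.06, camera adjusted p = 0.686). In amino acid metabolism 9 of 59 rose and 10 fell (12 and 14 over the list alone), with a median of -0.08, a mean of 0.01 and a camera direction down (adjusted p = 0.686). Bhmt, which remethylates homocysteine, rose by 1.62 ± 0.22 (adjusted p = 5.85e-05), and Gatm, the first enzyme of creatine synthesis, fell by 1.20 ± 0.20 (adjusted p = 0.000371). HIF targets outside glycolysis numbered 5 higher and 7 lower of 36 (8 and 9 over the list alone; median 0.01, camera adjusted p = 0.748).

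Ketone body genes rose for 3 of 10 and fell for 2 (4 and 2 over the list alone; median 0.23, camera adjusted p = 0.686). Oxct1, which uses ketone bodies, fell by 0.81 ± 0.08 (adjusted p = 4.37e-06). In gluconeogenesis and fructose metabolism 2 of 12 rose and 4 fell (2 and 5 over the list alone; median -0.12, camera adjusted p = 0.686): Pck1, the rate-limiting enzyme of gluconeogenesis, rose by 1.17 ± 0.17 (adjusted p = 0.00013), and the fructose transporter Slc2a5 fell by 0.95 ± 0.18 (adjusted p = 0.00123). Proximal tubule transporters rose for 7 of 38 and fell for 11 (7 and 12 over the list alone; median -0.12, camera adjusted p = 0.723). The glucose transporter Slc2a2 rose by 1.37 ± 0.15 (adjusted p = 8.36e-06) and the cation transporter Slc22a2 fell by 2.00 ± 0.22 (adjusted p = 9.14e-06). Slc5a2, the sodium-glucose cotransporter SGLT2, differed by -0.38 ± 0.14 and did not pass (adjusted p = 0.0672). The fixed genes Vegfa, Egln3, Slc2a1, Pdk1, Hif1a and Epas1 did not pass either, with differences of -0.08, -0.46, -0.37, 0.31, -0.01 and -0.01. Epo, the gene of erythropoietin, was well above background on 1 array and was not tested.

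Injury genes formed the other large group. Of 28 tubular injury genes 17 rose and 2 fell, with a median of 0.80 (18 and 2 over the list alone; camera adjusted p = 9.15e-11, and adjusted p = 0.241 with an estimated correlation). Besides Havcr1, Cdkn1a, the cell cycle inhibitor p21, rose by 3.33 ± 0.27 (adjusted p = 4.07e-07), Lcn2, the injury marker NGAL, by 1.69 ± 0.45 (adjusted p = 0.0148), and the keratin Krt8 by 0.81 ± 0.10 (adjusted p = 2.39e-05). Lcn2 differed by 1.29 with slide row as a covariate (adjusted p = 0.0591). Tff3 was among the members that fell. NRF2 and antioxidant genes rose for 11 of 32 and fell for 2 (12 and 3 over the list alone; median 0.16, camera adjusted p = 0.000584, and adjusted p = 0.241 with an estimated correlation), with Gsta3, a glutathione transferase, up by 1.76 ± 0.22 (adjusted p = 2.83e-05) and Txnip, a glucose-responsive inhibitor of thioredoxin, up by 1.40 ± 0.13 (adjusted p = 1.36e-06). On slide 3, which held 1 Sham array, the median of the antioxidant list was 0.08. Markers of the thick ascending limb fell for 5 of 11 and rose for 1 (8 and 1 over the list alone; median -0.40, camera adjusted p = 0.00115, and adjusted p = 0.241 with an estimated correlation): Egf fell by 0.92 ± 0.12 (adjusted p = 3.97e-05) and Tmem207 by 1.40 ± 0.25 (adjusted p = 0.000885). In the angiotensin system 0 of 13 rose and 5 fell (1 and 8 over the list alone; median -0.55, camera adjusted p = 0.00572, and adjusted p = 0.202 with an estimated correlation).

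The lists in this paragraph did not pass for DKD against Sham. Collecting duct markers rose for 4 of 20 and fell for 4 (5 and 5 over the list alone; median 0.00, mean -0.01, direction up, adjusted p = 0.81), with the water channel Aqp4 up by 1.56 ± 0.21 (adjusted p = 5.19e-05) and the keratin Krt7 down, at -1.02 ± 0.08 (adjusted p = 4.14e-07). Podocyte markers rose for 1 of 15 and fell for 3, in both adjustments (median -0.07, adjusted p = 0.686). Iron handling genes rose for 8 of 22 and fell for 2 (8 and 3 over the list alone; median 0.15, adjusted p = 0.106). They passed upward with normexp and quantile normalisation, quantile normalisation alone and the authors' value table (adjusted p = 0.0374, 0.0425 and 0.0466). Distal convoluted tubule markers rose for 2 of 9 and fell for 1 in both adjustments (median 0.23, adjusted p = 0.282, and 0.046 with a replicate block). Immediate early and heat shock genes rose for 6 of 21 and fell for 2 (7 and 2 over the list alone; median 0.05, adjusted p = 0.0827, and 0.0348 with the mean of probes), with the chaperone Hspa1a up by 0.75 ± 0.10 (adjusted p = 8.32e-05). Lipogenesis genes rose for 3 of 17 and fell for 4 (3 and 8 over the list alone; median -0.21, mean 0.06, direction down, adjusted p = 0.585). Clock genes rose for 2 of 15, cell cycle genes for 1 of 32 with 1 down, both also over the list alone, endothelial markers for 1 of 17 (0 over the list alone) and erythroid transcripts for 0 of 10 (adjusted p = 0.686, 0.723, 0.735 and 0.438; the clock median was -0.02, its mean 0.03 and its direction up). The cell cycle list passed upward on slide 1 (median 0.43, adjusted p = 9.46e-06), while its median was -0.62 on slide 3, which held 1 Sham array. It passed downward within row 1 and with slide row as a covariate (adjusted p = 0.0176 and 0.0266). Upward calls were also reached on slide 1 by iron handling (adjusted p = 0.0194) and on slides 1 and 2 by erythroid transcripts (adjusted p = 0.0464 and 0.0201). Slides 1 and 2 each held a DKD array in row 2, while all Sham arrays lay in row 1. DKD arrays of row 2 exceeded those of row 1 by a median of 1.34 for erythroid transcripts and 0.05 for iron handling. Within row 1 the medians of DKD against Sham were -0.12 and 0.12.

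In all, 4140 of 24217 genes (17.1%) passed an adjusted p of 0.05 in limma, 1943 higher and 2197 lower in DKD. A fold of at least 2 was reached by 893 of them. The groups did not overlap at 2386 of the 4140. Chance gives 0.253% for genes not chosen by their difference, which is no baseline for these called genes. With background correction by normexp and quantile normalisation 34.7% of the changed genes were higher, against 46.9% here. Of 1011 changed genes with several probes, 6 had another probe past the threshold the opposite way. Slide as a block gave 5453 genes, of which 4040 were among the 4140, and the replicate number as a block gave 3341. Within single slides limma gave 0 and 2 genes on slides 1 and 2 (4217 and 3648 at an unadjusted p under 0.05). Slide 3 held 1 Sham array, so no count is given for it. Without the DKD arrays of row 2 the count was 3171.

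The comparison of DKD+enarodustat with DKD asked what the drug changed in diabetic kidneys. Glycolytic and HIF-responsive genes rose. Mgarp, a HIF-responsive mitochondrial protein, rose by 3.70 ± 0.26 on the log2 scale (SE, n = 7 and 7, adjusted p = 1.97e-07), from 3 of 7 DKD arrays above background to 7 of 7, and by 1.23 with normexp and quantile normalisation. Slc16a3, the lactate exporter MCT4, rose by 2.32 ± 0.22 (adjusted p = 1.04e-05), and Ldha rose by 1.12 ± 0.08 (adjusted p = 3.93e-07). For each of these genes every DKD+enarodustat array lay above every DKD array. Havcr1 differed by 0.10 ± 0.59 and did not pass (adjusted p = 0.986). Over the alternatives its difference ranged from -1.21 to 1.45, without a call in any. Its normalised log2 level was -0.11 and -0.56 on the 2 DKD arrays of row 2. On the DKD arrays of row 1 it was -3.97 to -0.53, so the difference depends on slide row or on these animals. The rn4 probes lay at 140282421 to 140282480 on chromosome 2 for Mgarp, at 110163119 to 110163178 on chromosome 10 for Slc16a3, and at 97412488 to 97412547 on chromosome 1 for Ldha.

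Of 19 glycolysis genes 13 rose and 0 fell, with a median of 0.54 (13 and 1 over the list alone; camera adjusted p = 4.02e-29, and adjusted p = 0.000203 with an estimated correlation). Pfkl, a phosphofructokinase, rose by 1.02 ± 0.11 (adjusted p = 4.02e-05), Gpi, glucose-6-phosphate isomerase, by 0.80 ± 0.08 (adjusted p = 4.02e-05), Eno1 by 0.59 ± 0.10 (adjusted p = 0.00206) and the glucose transporter Slc2a1 by 0.77 ± 0.12 (adjusted p = 0.00147). The aldolase Aldoc, which the list does not hold, rose by 1.54 ± 0.13 (adjusted p = 2.77e-06). HIF targets outside glycolysis rose for 16 of 36 and fell for 0, with a median of 0.36 (20 and 0 over the list alone; camera adjusted p = 8.07e-24, and adjusted p = 1.12e-06 with an estimated correlation). Among these, Bnip3, a mitophagy receptor, rose by 0.66 ± 0.06 (adjusted p = 1.04e-05), the collagen prolyl hydroxylase P4ha1 by 0.87 ± 0.10 (adjusted p = 7.38e-05), Pdk1, which inhibits pyruvate dehydrogenase, by 1.01 ± 0.13 (adjusted p = 0.000351) and Egln3, a HIF prolyl hydroxylase, by 0.84 ± 0.16 (adjusted p = 0.00667).

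The collagen lysyl hydroxylase Plod1 and the glycogen synthase Gys1, from the same HIF list, rose by 0.59 ± 0.07 and 0.57 ± 0.07 (adjusted p = 8.16e-05 and 0.000179). Vegfa, the vascular growth factor, rose by 0.43 ± 0.10 (adjusted p = 0.0302, and 0.0882 with a replicate block), and leaving out any of 8 of the 19 arrays in turn ended its call, over a range of 0.38 to 0.49. The HIF subunit genes Hif1a and Epas1 differed by -0.24 ± 0.07 and 0.16 ± 0.07 and did not pass (adjusted p = 0.115 and 0.33). Within slides 1, 2 and 3 the glycolysis median was 0.54, 0.61 and 0.49 and that of the HIF targets 0.34, 0.41 and 0.32. Within slide row 2, which held 7 DKD+enarodustat and 2 DKD arrays, these medians were 0.55 and 0.41. With slide row as a covariate, Mgarp, Slc16a3, Ldha, Aldoc, Pfkl, Gpi, Bnip3, P4ha1, Plod1 and Gys1 kept an adjusted p under 0.05, while Eno1, Slc2a1, Pdk1, Egln3 and Vegfa did not, at differences of 0.55, 0.78, 0.83, 0.53 and 0.36 (adjusted p = 0.156, 0.0911, 0.0809, 0.511 and 0.512).

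**Figure D2:**
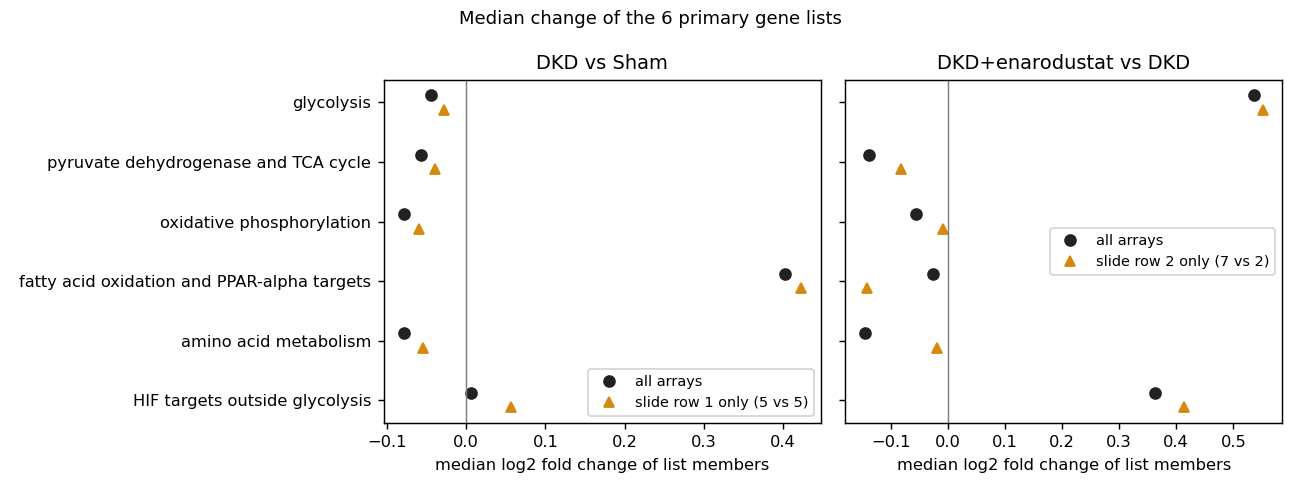
Median log2 fold change of the members of 6 gene lists (horizontal axis), for DKD against Sham on the left and DKD+enarodustat against DKD on the right. Circles use all arrays and triangles only the arrays of 1 slide row (5 against 5 in row 1, 7 against 2 in row 2). Fatty acid oxidation lies at 0.40 on the left, and glycolysis and HIF targets lie at 0.54 and 0.36 on the right.

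Few mitochondrial and amino acid genes passed with enarodustat, all of them lower, and the 3 downward list calls ended with an estimated correlation. Within slide row 2 the medians of the TCA cycle, oxidative phosphorylation and amino acid lists were -0.08, -0.01 and -0.02. Of 22 genes of pyruvate dehydrogenase and the TCA cycle 0 rose and 3 fell, with a median of -0.14 (0 and 10 over the list alone; camera adjusted p = 2.92e-06, adjusted p = 0.276 with an estimated correlation and 0.0944 with slide row as a covariate). The 3 were Idh3a, an isocitrate dehydrogenase subunit, by -0.31 ± 0.07, and Pdhb and Dld, subunits of the pyruvate dehydrogenase complex, by -0.31 ± 0.08 and -0.28 ± 0.07 (adjusted p = 0.0264, 0.0455 and 0.046, and 0.07, 0.0584 and 0.0584 with a replicate block). Leaving out 1 array at a time ended these calls for 7, 15 and 17 of the 19 arrays. In oxidative phosphorylation 0 of 55 rose and 1 fell, with a median of -0.06 (0 and 4 over the list alone; camera adjusted p = 0.0056). This call ended with an estimated correlation (adjusted p = 0.755), with slide row as a covariate (adjusted p = 0.644), and without DKD replicate 1 or DKD+enarodustat replicate 4 (adjusted p = 0.0552 and 0.0821). It was stronger with normexp and quantile normalisation, quantile normalisation alone and the authors' value table (camera adjusted p = 1.47e-06, 1.35e-07 and 6.82e-06). The gene that fell was Uqcrc2, a core subunit of complex III, by 0.31 ± 0.05 (adjusted p = 0.00289, and 0.0594 with a replicate block). Amino acid metabolism had 0 of 59 up and 2 down, with a median of -0.15 (0 and 2 over the list alone; camera adjusted p = 1.63e-05, adjusted p = 0.276 with an estimated correlation and 0.557 with slide row as a covariate). Its 2 genes, Acad8 of valine breakdown and Mut, methylmalonyl-CoA mutase, fell by 0.32 ± 0.06 and 0.30 ± 0.07 (adjusted p = 0.0105 and 0.041, and 0.0537 and 0.164 with a replicate block). The calls of Idh3a, Pdhb, Dld, Uqcrc2, Acad8 and Mut ended with slide row as a covariate, at -0.20, -0.21, -0.16, -0.19, -0.21 and -0.17 (adjusted p = 0.649, 0.685, 0.731, 0.408, 0.52 and 0.74).

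Fatty acid oxidation and PPAR-alpha targets, the list with the most genes past the threshold for DKD against Sham, held 0 genes past the threshold in either direction with limma (4 up and 6 down at an unadjusted p under 0.05; median -0.03, camera adjusted p = 0.895), and within slides 1, 2 and 3 their median was 0.01, -0.21 and 0.03. With slide row as a covariate their camera adjusted p was 0.0402, downward. Pdk4 and Cpt1a differed by 0.52 ± 0.23 and -0.22 ± 0.19 (adjusted p = 0.328 and 0.725). Lipogenesis genes fell for 1 of 17 and rose for 0, with a median of -0.21 (3 and 0 over the list alone; camera adjusted p = 0.0056, and adjusted p = 0.0499 with an estimated correlation). The gene was the desaturase Fads2, by 0.58 ± 0.08 (adjusted p = 0.000368). It differed by -0.46 with slide row as a covariate (adjusted p = 0.0911) and by -0.38 with normexp and quantile normalisation. The lipogenesis call ended with the authors' value table (adjusted p = 0.0591), without the DKD arrays of row 2 (adjusted p = 0.0845) and on slides 1 and 3 (adjusted p = 0.0695 and 0.141). With slide row as a covariate it was stronger (camera adjusted p = 7.07e-06). The 28 tubular injury genes included 1 that rose and 1 that fell (1 and 1 over the list alone; median 0.05, camera adjusted p = 0.372). Their list passed downward with slide row as a covariate and within row 2 (adjusted p = 0.00357 and 0.00274), both against the same 2 DKD arrays. It passed upward without the DKD arrays of row 2 and on slide 3 (adjusted p = 0.00506 and 0.00268). Lcn2, Txnip, Slc2a2, Pck1 and Slc5a2 differed by 0.37, 0.12, -0.16, -0.14 and -0.05 and none of them passed. Over the alternatives Lcn2 ranged from -0.811 to 1.395, without a call in any.

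Other large rises were RT1-T24-3, a major histocompatibility gene, by 2.11 ± 0.33 (adjusted p = 0.00147, and 0.0516 with a replicate block), Rgs11, a regulator of G-protein signalling, by 1.85 ± 0.21 (adjusted p = 7.55e-05, and 0.54 with normexp and quantile normalisation), Apoc3, an apolipoprotein, by 1.14 ± 0.16 (adjusted p = 0.000514) and Tmem252, 2.15-fold (log2 SE 0.19, adjusted p = 0.00341). The other probe of RT1-T24-3 gave 0.10. The largest falls among genes whose groups did not overlap were Plppr4, named Lppr4 in the files, by 0.91 ± 0.12 (adjusted p = 0.00043), Pde4dip, by 0.89 ± 0.15 (adjusted p = 0.00259), and the lipid kinase gene Pip5k1b, by 0.68 ± 0.13 (adjusted p = 0.00824, and 0.0505 with a replicate block). Fads2 was also among them. Gtf3c3, Fam98a, Akirin1 and Fastkd5 fell by 0.50, 0.48, 0.46 and 0.45 (adjusted p = 0.00103, 0.000825, 0.00109 and 0.00374), and a replicate block ended the call of Gtf3c3 (adjusted p = 0.0549). With slide row as a covariate Rgs11, Gtf3c3, Fam98a and Akirin1 kept their calls, while RT1-T24-3, Apoc3, Tmem252, Plppr4, Pde4dip, Pip5k1b and Fastkd5 did not, at 1.88, 1.15, 0.89, -0.85, -0.66, -0.75 and -0.44 (adjusted p = 0.155, 0.051, 0.288, 0.0664, 0.304, 0.149 and 0.171). The falls of Plppr4, Pip5k1b, Gtf3c3 and Fastkd5 were -0.26, -0.23, -0.16 and -0.27 with normexp and quantile normalisation, and those of Pde4dip and Akirin1 -0.57 and -0.28 in the authors' value table.

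The lists in this paragraph did not pass for DKD+enarodustat against DKD. Proximal tubule transporters and the angiotensin system each held 1 gene that fell (adjusted p = 0.716 for both; the latter had a median of -0.01, a mean of 0.08 and an upward direction), and immediate early genes 1 that rose (adjusted p = 0.156). Past the threshold with limma were 0 genes of the cholesterol, gluconeogenesis, ketone, extracellular matrix, podocyte, thick ascending limb, distal convoluted tubule, collecting duct, erythroid, adipocyte, unfolded protein and clock lists. At an unadjusted p under 0.05 these held 3, 4, 1, 0, 1, 1, 0, 5, 0, 0, 4 and 1, and their camera adjusted p was 0.716, 0.0725, 0.116, 0.939, 0.939, 0.276, 0.817, 0.101, 0.116, 0.716, 0.835 and 0.156. The extracellular matrix median was -0.06 and the podocyte median -0.03, with a mean of 0.03, while both directions were up. The adipocyte list passed downward with slide row as a covariate (adjusted p = 7.07e-06) and the thick ascending limb list upward on slide 1 (adjusted p = 0.0226), and the extracellular matrix list passed downward within row 2 (median -0.16, adjusted p = 0.0327). Without the DKD arrays of row 2 the gluconeogenesis and ketone lists passed downward and the erythroid list upward (adjusted p = 0.0187, 0.0187 and 0.00214). The gluconeogenesis list also passed downward with normexp and quantile normalisation, quantile normalisation alone, the mean of probes and no filter on dim probes (adjusted p = 0.0315, 0.0237, 0.0342 and 0.00424). With no such filter the ketone, proximal tubule and collecting duct lists passed downward as well (adjusted p = 0.0146, 0.0313 and 0.00282). The median of all genes was then 0.047, against -0.023 in the main fit, so calls with no filter are set against a higher level of all genes.

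Across all genes, 485 of 24217 (2%) passed in limma, 259 higher and 226 lower with enarodustat, and 119 of them had a fold of at least 1.5, 98 higher and 21 lower. The groups did not overlap at 243 of the 485. Chance gives 0.0583% for genes not chosen by their difference, which is no baseline for these called genes. The share of changed genes that were higher was 53.4% here, 69.5% with arrays centred on their median and 34.3% with the authors' value table. Slide as a block gave 915 genes, including all 485, and a replicate block gave 190, of which 156 were among the 485 and 82.6% were higher. Slide row as a covariate left 84 genes, 47 of them among the 485, and within row 2 alone 12 passed. Single slides gave 1, 0 and 0 genes (1713, 1880 and 2619 at an unadjusted p under 0.05). Without DKD replicate 6 the count was 286.

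The comparison of DKD+enarodustat with Sham asked what still differed from non-diabetic kidneys under the drug. Havcr1 was higher than in Sham by 4.99 ± 0.65 (SE, n = 7 and 5, adjusted p = 2.65e-05), by 2.59 with normexp and quantile normalisation and by 2.33 in the authors' value table. Pdk4 was higher by 3.29 ± 0.25 (adjusted p = 1.04e-07, and 0.65 on the log2 scale with normexp and quantile normalisation), Ldha by 1.77 ± 0.09 (adjusted p = 1.1e-09), Txnip by 1.52 ± 0.13 (adjusted p = 3.24e-07) and Pdk1 by 1.32 ± 0.14 (adjusted p = 4e-06). Slc2a2, Pck1 and Lcn2 were higher by 1.21, 1.04 and 2.06 (adjusted p = 1.74e-05, 0.000243 and 0.00265). Slc2a1 was higher by 0.40 ± 0.13 (adjusted p = 0.0343) and Hif1a lower, at -0.25 ± 0.08 (adjusted p = 0.0275). Vegfa, at 0.35 ± 0.11, and Slc5a2, at -0.42 ± 0.14, passed here (adjusted p = 0.0231 and 0.0295) and not with a replicate block (adjusted p = 0.0529 and 0.0539). Cpt1a, Egln3 and Epas1 differed by 0.56, 0.38 and 0.15 and did not pass (adjusted p = 0.0584, 0.121 and 0.167), and with a replicate block Egln3 passed (adjusted p = 0.0395). Ldha, Pdk1, Pdk4, Slc2a2 and Txnip kept their calls with slide row as a covariate, while Havcr1, Lcn2, Pck1, Slc2a1, Hif1a, Vegfa and Slc5a2 did not, at 3.31, 0.64, 0.88, 0.41, -0.26, 0.25 and -0.05 (adjusted p = 0.0889, 0.701, 0.118, 0.412, 0.394, 0.555 and 0.927).

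Glycolysis genes rose for 14 of 19 and fell for 1 (14 and 2 over the list alone; median 0.60, camera adjusted p = 2.55e-09, and adjusted p = 0.0515 with an estimated correlation). HIF targets rose for 15 of 36 and fell for 2 (15 and 2 over the list alone; median 0.30, camera adjusted p = 7.14e-08), and this call alone of the 20 lists past the threshold held with an estimated correlation (adjusted p = 0.00166). Fatty acid oxidation genes rose for 22 of 43 and fell for 3 (26 and 3 over the list alone; median 0.48, camera adjusted p = 2.72e-09, and adjusted p = 0.249 with an estimated correlation). Tubular injury genes rose for 20 of 28 and fell for 2 (20 and 2 over the list alone; median 0.80, camera adjusted p = 9.12e-10, and adjusted p = 0.137 with an estimated correlation). Oxidative phosphorylation fell for 17 of 55, amino acid metabolism for 23 of 59 with 5 up, and the TCA cycle list for 9 of 22 (19, 26 with 5 up, and 11 over the list alone; medians -0.13, -0.23 and -0.18; camera adjusted p = 3e-04, 0.0147 and 0.00509, and adjusted p = 0.4 for each with an estimated correlation). With slide row as a covariate those calls on oxidative phosphorylation, amino acid and TCA cycle genes ended (adjusted p = 0.092, 0.755 and 0.37).

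Against Sham, DKD+enarodustat also differed in leukocyte (10 up, 0 down), antioxidant (12 and 5), iron (8 and 2), extracellular matrix (8 and 1), adipocyte (3 and 0), cell cycle (5 and 1), immediate early (7 and 2) and erythroid lists (0 and 0), upward, with camera adjusted p of 0.000369, 0.00351, 0.0157, 0.0164, 0.00681, 0.00329, 0.0147 and 0.0497. Downward were cholesterol synthesis (2 up, 11 down), lipogenesis (2 and 8), thick ascending limb (1 and 5), angiotensin system (0 and 6) and unfolded protein lists (1 and 9), with 0.0147, 0.0459, 0.0157, 0.0157 and 0.0265. With an estimated correlation none of these 13 calls held: the upward lists had adjusted p = 0.39, 0.249, 0.114, 0.407, 0.315, 0.407, 0.249 and 0.488, and the downward lists 0.39, 0.205, 0.39, 0.137 and 0.307. A replicate block ended the cholesterol and lipogenesis calls (adjusted p = 0.0712 and 0.114), and slide as a block the latter (adjusted p = 0.085). The authors' value table ended the cholesterol, lipogenesis and unfolded protein calls (adjusted p = 0.109, 0.128 and 0.0606). No filter on dim probes ended the antioxidant, iron, extracellular matrix, cell cycle, immediate early and erythroid calls (adjusted p = 0.122, 0.239, 0.239, 0.111, 0.165 and 0.247). Slide row as a covariate ended the leukocyte, iron, extracellular matrix, immediate early and thick ascending limb calls (adjusted p = 0.384, 0.373, 0.754, 0.126 and 0.0521), and it ended and turned downward the adipocyte, cell cycle and erythroid calls (adjusted p = 0.433, 0.0702 and 0.373). The gluconeogenesis, ketone, proximal tubule, podocyte, distal tubule, collecting duct, endothelial and clock lists did not pass (adjusted p = 0.116, 0.986, 0.446, 0.706, 0.29, 0.417, 0.164 and 0.198, and 0.0328 for the endothelial list with a replicate block); the ketone median was 0.16 with a downward direction and the podocyte median 0.03 with a mean of -0.03.

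In total 6311 genes (26.1%) passed, 2429 higher and 3882 lower than in Sham, and the groups did not overlap at 3388 of them. Chance gives 0.253% for genes not chosen by their difference, which is no baseline for these called genes. Slide as a block gave 7976 genes. Within slides 1 and 2 limma gave 14 and 46, and slide 3 held only 1 Sham array. Slide row could not be separated within a row here, since all Sham arrays lay in row 1 and all DKD+enarodustat arrays in row 2; with row as a covariate, informed by the DKD arrays alone, 1032 genes passed.

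Whether enarodustat moved the diabetic changes back was asked across genes. Of the 4140 genes changed in DKD, 1928 (46.57%) had a DKD+enarodustat against DKD difference of the opposite sign. Because both comparisons use the DKD arrays, unchanged groups simulated on the same design gave 81.09% (80.05% to 82.03% over 20 simulations) for as many leading genes. The simulated genes carried no DKD effect and were picked on noise alone, which raises the opposite-sign share. That value is therefore not the share to expect for the 4140 genes. With the 7 DKD arrays split into 3 and 4, so that no array served both comparisons, the share had a median of 39% over 70 splits (28.25% to 52.28%). Past the threshold in both comparisons were 160 genes, 47 moving the opposite way and 113 the same way. Independent lists would give 18.1 genes up and then down, 23.5 down and then up, 20.8 up in both and 20.5 down in both, against 15, 32, 85 and 28 seen. Independence does not hold here, because both comparisons use the DKD arrays and slide row was tied to group. These counts therefore cannot separate an effect of the drug from one of slide row. Across genes, which are not independent replicates, the fold changes correlated at -0.06 (simulated -0.46), with a covariance of -0.00794 against -0.0327 simulated. The simulations leave out slide, which is nearly balanced across the groups, so they overstate what shared arrays give, and the splits unbalance the slides. With slide in the fit, a setting chosen after seeing the data, the covariance was -0.00862 against -0.0217 from the residual variance alone.

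Among the genes past the threshold in both, those that reversed most were named by a fixed rule. Eno1 and Slc11a2, an iron transporter, fell in DKD (Slc11a2 by 0.70 ± 0.14, adjusted p = 0.00181) and rose with enarodustat (Slc11a2 by 0.64 ± 0.13, adjusted p = 0.0101). Pde4dip rose by 0.90 ± 0.16 in DKD (adjusted p = 0.000894) and fell with the drug. Maob, monoamine oxidase B, rose by 0.66 ± 0.17 in DKD (adjusted p = 0.0131) and fell by 0.73 ± 0.16 with enarodustat (adjusted p = 0.0189, and 0.102 with a replicate block). RT1-T24-3, the interferon-induced gene Oasl2 and Arhgef39 fell in DKD by 1.22, 0.93 and 0.73 (adjusted p = 0.0275, 0.0388 and 0.0474) and rose with enarodustat by 2.11, 1.26 and 1.07. A replicate block ended the DKD calls of Oasl2 and Arhgef39 (adjusted p = 0.0606 and 0.14) and the enarodustat call of Oasl2 (adjusted p = 0.154). Leaving out 1 array ended the DKD call of these genes in 4, 8 and 12 of 19 cases, and leaving out DKD replicate 6 ended the enarodustat call of Oasl2 (adjusted p = 0.052). Slfn1 was above background on 0 DKD arrays, so it was at least 1.19-fold lower in DKD than in Sham and at least 1.78-fold higher with enarodustat than in DKD (adjusted p = 0.0461 and 0.0191). The first call ended on leaving out any of 14 of the 19 arrays, and the second with a replicate block (adjusted p = 0.12) and without DKD replicate 6 (adjusted p = 0.0517). The enarodustat calls of Eno1, Slc11a2, Pde4dip, Maob, RT1-T24-3, Oasl2 and Arhgef39 ended with slide row as a covariate, at 0.55, 0.59, -0.66, -0.60, 1.88, 0.86 and 0.50 (adjusted p = 0.156, 0.304, 0.304, 0.473, 0.155, 0.583 and 0.706). That of Slfn1 ended too (adjusted p = 0.59). The calls of Slfn1 and Arhgef39 in both comparisons also ended with normexp and quantile normalisation (adjusted p = 0.0834 and 0.0808 in DKD, 0.138 and 0.07 with enarodustat), where Maob differed by 0.31 and -0.42.

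Other genes moved further in the diabetic direction under enarodustat. Ldha and Aldoc rose in both steps, Aldoc by 0.91 ± 0.14 in DKD (adjusted p = 0.000281, and 0.58 with normexp and quantile normalisation). Bnip3 rose by 0.46 ± 0.07 in DKD (adjusted p = 0.000154) before its further rise with the drug, and Apoc3 rose by 0.76 ± 0.17 in DKD (adjusted p = 0.00459). Adh1c, an alcohol dehydrogenase named Adh1 in the files, rose by 1.26 ± 0.24 and then by 0.98 ± 0.22 (adjusted p = 0.00158 and 0.0265). The galactokinase Galk1 rose by 0.59 ± 0.11 and then by 0.71 ± 0.10 (adjusted p = 0.00131 and 0.000676), and Btg2, an antiproliferative gene, by 0.50 ± 0.13 and then by 0.68 ± 0.12 (adjusted p = 0.0124 and 0.0038, and 0.0514 for the first with a replicate block). Tph1, a tryptophan hydroxylase, fell by 0.86 ± 0.19 and then by 0.71 ± 0.17 (adjusted p = 0.00437 and 0.0427, and 0.122 for the second with a replicate block), and was above background on 1 of 7 DKD+enarodustat arrays. The differences of Tph1 were -0.18 and -0.11 with normexp and quantile normalisation (adjusted p = 0.00785 and 0.199). With slide row as a covariate the enarodustat calls of Ldha, Aldoc and Bnip3 held, and those of Apoc3, Adh1c, Galk1, Btg2 and Tph1 ended, at 1.15, 0.89, 0.61, 0.55 and -0.95 (adjusted p = 0.051, 0.442, 0.109, 0.3 and 0.156).

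**Figure D3:**
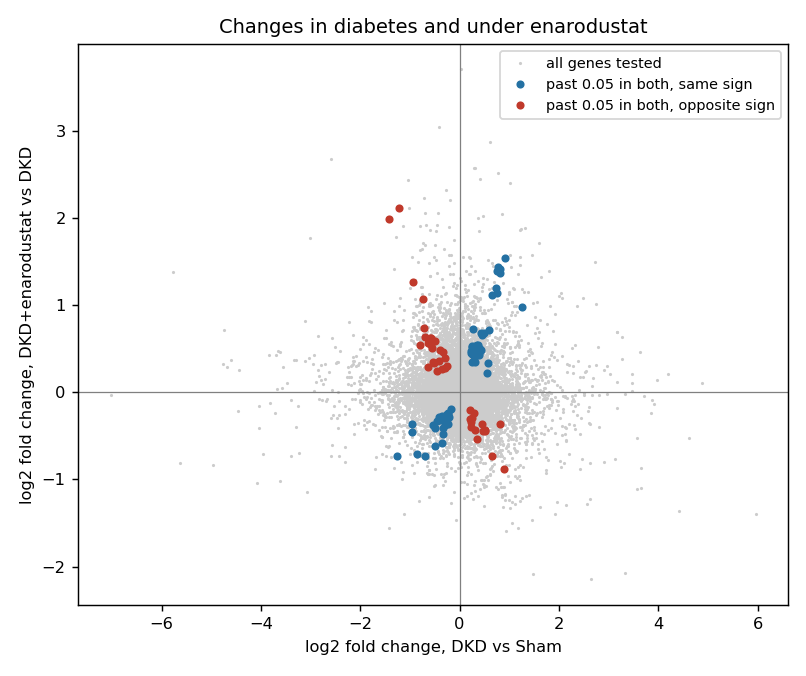
Log2 fold change of DKD against Sham (horizontal axis) and of DKD+enarodustat against DKD (vertical axis), 1 point per gene, for 24217 genes. Among the 160 genes past the threshold in both comparisons, 113 with the same sign are blue and 47 with opposite signs are red.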

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

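All gaps below were found by a test set before the data were examined: the distance of a group's highest or lowest array to its nearest neighbour, over the group's range, against Dixon's critical value. The set of named genes grew after a first count of such gaps. The test covered 375 groups of arrays, of which 17 passed it, where chance at 5% would give about 18.8; Sham replicate 2 held 3 of them, the most on 1 array.

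In log2 units, Creb3l3 was -2.46 in DKD replicate 4, with the other DKD arrays from -4.32 to -3.59. Cyp2c11 was 1.06 in Sham replicate 2, with the others from -0.66 to -0.18, and on the same array Cyp4a1 was 2.13 (others 1.03 to 1.17) and Gatm 2.08 (others 2.9 to 3.18). In DKD replicate 2, Krt8 was -0.18 (others 0.07 to 0.25) and Kl, the gene of the hormone coreceptor klotho, was -0.62 (others -0.38 to -0.21). Txnip was 0.69 in Sham replicate 3 (others 1.16 to 1.26). Cycs, cytochrome c, was 3.22 in DKD+enarodustat replicate 6 (others 4.62 to 5.04). Ldha was 4.72 in DKD replicate 6 (others 5.01 to 5.13), an array whose level still lay below all DKD+enarodustat arrays. Tm7sf2 was -0.81 in DKD+enarodustat replicate 4 (others -0.33 to -0.1), and Sdf2l1 was -1.45 in DKD+enarodustat replicate 7 (others -0.89 to -0.61). Tph1 was -7.26 in DKD replicate 7 (others -6.43 to -6.04), Plppr4 was -4.64 in DKD replicate 5 (others -5.3 to -5.2), and Fastkd5 was -3.5 in DKD replicate 3 (others -3.7 to -3.63). Mut was 2.14 in Sham replicate 4 (others 2.35 to 2.38). The mean of the fatty acid oxidation list was 1.36 in DKD+enarodustat replicate 4 (others 1.73 to 1.98), and that of the amino acid list was 1.53 in Sham replicate 5 (others 1.61 to 1.65). No explanation of these single arrays was tested.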

How the results depend on the processing

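The alternatives with slide row, slide with slide row, 1 slide row, a single slide or without the DKD arrays of row 2 were chosen after seeing the data, and all others before. Across all alternatives, 433 of 468 values of the 6 main lists in the comparisons of DKD with Sham and DKD+enarodustat with DKD, 95 of 122 gene counts and all 35 values of the opposite-sign share kept their direction and side of the threshold, or stayed within 1.5 times or the spread. That share ranged from 39% to 51.44%; its spread, a jackknife SD of 8.86, was also chosen after seeing the data. Among 6460 values of named genes 855 lost and 69 gained a call and 0 reversed. Among 2780 values of the other 22 lists, and of the 6 main lists for DKD+enarodustat against Sham, 148 lost a call, 47 gained one and 22 reversed. For named genes past the threshold, slide as a block kept 76 of 77 for DKD against Sham, 48 of 48 for DKD+enarodustat against DKD and 13 of 13 for DKD+enarodustat against Sham, and slide row as a covariate kept 71, 14 and 6. The cause was not tested for any change below. By construction, however, single slides, 1 slide row, the replicate block, only the groups compared, leaving out arrays and stricter thresholds use fewer arrays or calls. The totals above and the values below include fits on slide 3, where Sham had 1 array. Those fits against Sham cannot decide a call or a count, since 1 array has no spread of its own.

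For DKD against Sham, the TCA cycle list passed downward with normexp and quantile normalisation (adjusted p = 0.0276) and with the authors' value table (0.0466). Oxidative phosphorylation lost its call with median centring (0.0786), slide row as a covariate (0.0715), slide and slide row (0.164), row 1 only (0.0687), without the row 2 arrays (0.0836), on slides 1 and 3 (0.747 and 0.0903) and with an estimated correlation (0.84), and leaving out each array gave 0.00424 to 0.0618. The slide 3 value rests on 1 Sham array, so it does not test the oxidative phosphorylation call. The median of that list on slide 3 was -0.09. Fatty acid oxidation lost its call only with an estimated correlation (0.241). The count of 4140 became 1825 with a fold of at least 1.5, 2211 at an adjusted p under 0.01, and 0, 2 and 142 on slides 1, 2 and 3. On slide 1 the camera direction of cholesterol synthesis was up (0.946), although its median was -0.088. The cell cycle passed upward there (9.46e-06).

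For DKD+enarodustat against DKD, the count of 485 became 1775 with the authors' value table, 284 with no filter on dim probes, 276 with only the groups compared, 915 with slide as a block, 190 with a replicate block, 84 with slide row, 242 with slide and slide row, 12 in row 2 only, 1, 0 and 0 on slides 1, 2 and 3, 119 with a fold of at least 1.5, 198 at an adjusted p under 0.01 and 286 to 497 on leaving out each array (286 without DKD replicate 6). For the TCA cycle list adjusted p was 0.0944 with slide row, 0.171 with slide and slide row, 0.086 in row 2, 0.0608 on slide 1 and 0.276 with an estimated correlation. For oxidative phosphorylation it was 0.644, 0.859 and 0.68 in the same slide row settings, 0.403, 0.0706 and 0.0856 on slides 1, 2 and 3, 0.755 with an estimated correlation and 0.000327 to 0.0821 on leaving out each array. Amino acid metabolism gave 0.557, 0.859 and 0.503 with the slide row settings, 0.567 on slide 1 and 0.276 with an estimated correlation. Fatty acid oxidation gained a downward call with no filter (0.0491), with slide row (0.0402) and in row 2 (0.0327). With no filter its median was -0.028, against -0.025 in the main fit. The median of all genes was then 0.047, against -0.023 in the main fit, so that call does not show a fall of the list itself. The camera direction turned downward with slide row, slide and slide row, and row 2 only for tubular injury (0.00357, 0.0151 and 0.00274), leukocyte markers (0.447, 0.741 and 0.369) and the cell cycle (0.789, 0.943 and 0.831). The cell cycle medians stayed positive in these settings, at 0.029, 0.037 and 0.029. All of these settings rest on the 2 DKD arrays of row 2 to separate row from drug. The extracellular matrix list also turned downward in row 2 (0.0327), the cell cycle on slide 1 (0.942) and leukocyte markers on slide 2 (0.166), while tubular injury passed upward without the row 2 arrays (0.00506) and on slide 3 (0.00268).

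For DKD+enarodustat against Sham, the count of 6311 became 10746 with no filter on dim probes, where the median of all genes lay 0.10 above 0, 1032 with slide row, 1431 with slide and slide row, 14, 46 and 338 on slides 1, 2 and 3, 2617 with a fold of at least 1.5 and 3753 at an adjusted p under 0.01. With slide row and with slide and slide row, the cell cycle (0.0702 and 0.25), erythroid (0.373 and 0.978) and adipocyte lists (0.433 and 0.879) turned downward. Amino acid metabolism turned upward with slide and slide row (0.821). The camera direction of cholesterol synthesis turned upward on slide 1 (0.771), although its median there was -0.066.

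Leaving out each array gave 3156 to 4339 genes for DKD against Sham, 5175 to 6513 for DKD+enarodustat against Sham and a share of 42.48% to 50.82%. Adjusted p for DKD against Sham was then 1.62e-15 to 2.68e-10 for fatty acid oxidation, and for DKD+enarodustat against DKD 1.34e-30 to 3.16e-25 for glycolysis, 1.68e-24 to 3.05e-20 for HIF targets, 2.45e-07 to 0.000142 for the TCA cycle and 1.89e-07 to 0.000289 for amino acid metabolism.

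The replicate block kept 66 of 77, 31 of 48 and 11 of 13 named calls in the 3 comparisons. It ended 2 list calls for DKD against Sham or DKD+enarodustat against DKD, cholesterol synthesis (0.0549) and leukocyte markers (0.113), gave a call to the distal convoluted tubule list (0.046), and changed the cholesterol (0.0712), lipogenesis (0.114) and endothelial (0.0328) calls for DKD+enarodustat against Sham; it changed no other list call. Scan date as a block was not run, since all arrays were scanned on 1 day, and 1 slide row could not be used for DKD+enarodustat against Sham. Lower signal over background in slide row 2 limits what dim probes can show in DKD+enarodustat.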

Other observations

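Among the tests below, those on bright probes, on shared DKD arrays and with slide in the fit were chosen after the result was seen, as were values given with slide row as a covariate. Genes outside energy metabolism and tubular injury also changed between DKD and Sham. Cholesterol synthesis genes fell for 9 of 23 and rose for 2 (13 and 3 over the list alone; median -0.27, camera adjusted p = 0.0139, adjusted p = 0.525 with an estimated correlation, 0.0603 with slide as a block and 0.0549 with a replicate block). The sterol enzyme Msmo1 fell by 0.35 ± 0.07 (adjusted p = 0.00139), while Tm7sf2, a sterol reductase, rose by 1.01 ± 0.12 (adjusted p = 1.99e-05). Genes of the unfolded protein response fell for 7 of 20 and rose for 1 (9 and 1 over the list alone; median -0.20, camera adjusted p = 0.0152, and adjusted p = 0.241 with an estimated correlation), among them the chaperone Hspa5, by 0.41 ± 0.09 (adjusted p = 0.00459), and Sdf2l1, by 0.87 ± 0.15 (adjusted p = 0.000675). Extracellular matrix genes rose for 7 of 26 and fell for 1 (8 and 1 over the list alone; median 0.17, camera adjusted p = 0.00947, adjusted p = 0.567 with an estimated correlation and 0.0634 with slide row), with the collagen crosslinking enzyme Lox up by 1.68 ± 0.18 (adjusted p = 5.55e-06, and 1.07 with normexp and quantile normalisation). Leukocyte markers rose for 5 of 30 and fell for 0 (5 and 0 over the list alone; median 0.27, camera adjusted p = 0.00783, adjusted p = 0.72 with an estimated correlation and 0.0576 with slide row), with Cd14 up by 0.82 ± 0.17 (adjusted p = 0.00207).

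With enarodustat, iron genes were mixed against DKD: 2 of 22 rose and 1 fell (4 and 1 over the list alone; median 0.05, camera adjusted p = 0.116, and upward calls at 0.0226 without the DKD arrays of row 2 and 0.0225 on slide 3). The transferrin receptor Tfrc rose 2.21-fold (log2 SE 0.27, adjusted p = 0.0359), the iron transporter Slc11a2 rose, and Iscu, an iron-sulfur cluster scaffold, fell by 0.24 ± 0.05 (adjusted p = 0.0156); a replicate block ended the calls of Tfrc and Iscu (adjusted p = 0.0905 and 0.146), and slide row as a covariate those of Tfrc, Iscu and Slc11a2, at 1.26, -0.25 and 0.59 (adjusted p = 0.311, 0.252 and 0.304). Of 32 cell cycle genes 0 passed with limma (18 up and 1 down at an unadjusted p under 0.05, 14 and 1 over the list alone), and their median was 0.48 (camera adjusted p = 8.29e-10, and adjusted p = 0.276 with an estimated correlation). That median was 0.03 within slide row 2, and DKD arrays of row 2 exceeded those of row 1 by 0.60. Endothelial markers held 0 of 17 past the threshold (4 up and 0 down unadjusted, 2 and 0 over the list alone; median 0.11, camera adjusted p = 0.00452, adjusted p = 0.276 with an estimated correlation and 0.159 with slide row), and leukocyte markers 0 of 30 (1 and 0 unadjusted; median 0.06, camera adjusted p = 0.0406, adjusted p = 0.755 with an estimated correlation, 0.0848 with slide as a block and 0.113 with a replicate block). With no filter on dim probes both calls ended (adjusted p = 0.208 and 0.399). The leukocyte call also ended with median centring and the mean of probes (adjusted p = 0.0554 and 0.0695), and on leaving out any of 5 of the 19 arrays. The thioredoxin reductase gene Txnrd1 fell by 0.53 ± 0.10 (adjusted p = 0.00453, and -0.60 with an adjusted p of 0.0945 with slide row) as 1 of 32 antioxidant genes (median -0.01, adjusted p = 0.956).

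The rise of glycolysis and HIF target genes with enarodustat was weighed against slide row and against dim probes. If row were the whole source, the 55 members would not differ within row 2, yet their median there was 0.445, near 0.43 over all arrays, and DKD arrays of row 2 differed from those of row 1 by -0.0384. The 53 members well above background on all 19 arrays gave 0.447. Of 100 splits of the arrays, drawn from 1716, only the real 1 reached a mean of 0.433. The highest other gave 0.337, so a chance split is an unlikely source. Both technical sources are argued against as the whole cause, and an effect of the drug on HIF signalling is a hypothesis that may account for the rise.

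The second pattern was that, over all arrays, fold changes of both comparisons ran the same way more than shared DKD arrays allow. With slide in the fit and the part given by residual variance taken off, the covariance was 0.0134 as the mean of 70 splits that share no array (-0.0102 to 0.0475) and 0.0131 with all arrays (0.00821 to 0.0191 on leaving out each array), which argues against shared arrays as the whole source if residuals are otherwise independent. Slide row is a candidate source: with DKD arrays of row 1 set against Sham and those of row 2 against DKD+enarodustat, the covariance was -0.00406, the 2nd lowest of the 21 ways to choose 2 arrays (lowest -0.00562, median 0.0183, highest 0.0693), and with slide in the fit and the residual part taken off it was -0.018, the lowest of those 21 (median 0.015, highest 0.0468). Of the 6 lists raised in DKD, adipocyte markers lay lower with enarodustat within row 2, with a median of -0.78, as did tubular injury, fatty acid oxidation and extracellular matrix with -0.25, -0.14 and -0.16 (adjusted p = 2.81e-05, 0.00274, 0.0327 and 0.0327), while antioxidant genes and leukocyte markers did not pass (adjusted p = 0.779 and 0.369). The row 2 DKD arrays also had the highest adipocyte marker levels, so row and animal cannot be separated there, and whether the drug carries diabetic changes further or partly back stays open.

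The third pattern was the rise of fatty acid oxidation and PPAR-alpha targets in DKD. Adipose tissue in the samples does not suffice as a source: with the mean of the adipocyte markers as a covariate the median of 43 genes was 0.428, against 0.403 without, although the count that rose dropped from 26 to 14 as the count of all changed genes dropped from 4140 to 2232. Within slide row 1 the median was 0.423, which argues against slide row. In 100 splits, drawn from 792, only the real 1 reached a list mean of 0.639, with 0.509 the highest other. Among the splits that part every numbered pair the highest other was 0.54, so a chance split is an unlikely source. A diabetic effect on lipid use may underlie the rise, as a hypothesis.

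For the gene counts, a chance split of the arrays is an unlikely source in each comparison. Only 100 of 792, 1716 and 792 possible splits were drawn. Slide row was not held fixed in them, so they do not separate row from group. The real counts of 4140, 485 and 6311 stood against highest others of 2389, 207 and 46 among 100 splits each, and only the real 1 was as large. The split with 2389 genes parted 0 of the numbered pairs and followed the slides (slide imbalance 0.8 against 0.229 in the real split), and with slide as a block the real comparison gave 5453. Among the splits that part every pair (32, 64 and 32), the highest others were 876, 4 and 525, again with only the real 1 as large. Within DKD, the arrays of row 2 differed from those of row 1 at 8 genes, against at most 4 for the other choices of 2 arrays.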
